A study of Mus musculus with 10 samples.

How the data were processed

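RNA was extracted with Trizol from urogenital systems dissected from mouse embryos at embryonic day 15.5, and biotin-labelled cRNA was made from 1 ug of total RNA of 1 to 2 urogenital systems, per the labels. Each genotype had 5 distinct pools of RNA, per the labels, so p-values measure the spread between pools. The series design text names an Affymetrix mouse genome array, but describes kidney mesenchyme isolated at an earlier stage from another Wnt9b allele, which the sample labels do not match; the groups here follow the sample labels. The genotype label of the control samples gives 1 cneo allele, whereas their titles and the series title call them wild type, and both readings were left open. The labels do not say what the cneo allele does to the Wnt9b transcript. Replicate numbers come from the titles.

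The deposited table holds 1 linear intensity per probe set and array, made by the authors. The mean of each array without its highest and lowest 2% of values was 500 on all 10 arrays, as global scaling of Affymetrix probe set summaries leaves it. The summarization method, background correction and software are not given in the sources used here. Of the 10 titles 4 end in CHP, the ending of Affymetrix summary files. These are homozygous pools 1 to 4, and no control title has this ending. Whether these arrays were handled apart from the rest is not given. Detection calls were not used here. Scaling of this kind fixes the trimmed mean of each array, so a change of total RNA per tissue is not measured, and dim probe sets carry most of the background noise. No pair of arrays held identical values. The median intensity ranged from 74.75 to 98.63 between arrays, and 19.9% to 23.0% of probe sets lay at or under the floor used. This share was 19.9% to 21.1% on homozygous arrays and 22.2% to 23.0% on control arrays, so it separated the genotypes, and its cause was not tested. Changes of genes near the floor cannot be told apart from this difference between arrays. The number of arrays limits the precision.

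Of 45101 probe sets, 64 Affymetrix controls were left out of tests. Probe sets were named through the platform annotation given with the series: 34945 had 1 gene symbol, 932 had several and 9160 had none here; names were taken from the first kind alone, and 0 symbols needed an update. Intensities below 16 were set to 16 and all values were taken to log2 for this work, so folds that involve floored arrays understate the change. Each of 18193 genes was represented by the probe set with the highest mean over all arrays. Among the 98 genes past the threshold that had more than 1 probe set, 21 had a probe set of opposite sign. Coordinates are those of the GRCm38.p6 gene table.

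Genotypes were compared with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with an intensity trend), two-sided, with Benjamini-Hochberg adjusted p under 0.05 and no block, since the labels name no pairing and no batch. The comparison was tested on simulated data drawn from each gene's mean over all arrays and its spread within genotypes, over 18193 genes with 100 changed at each size. In these data 40% of genes with a log2 change of 1 and 81% of genes with a log2 change of 2 were recovered, and 15 of 136 calls were false. Noise was drawn independently for each gene, so these rates do not cover variation that genes share between pools. Of 44 gene lists written before the data were examined, the 43 with 3 or more measured genes were tested with camera at a preset correlation of 0.01; 548 of 605 list entries matched a named gene. The lists cover nephron and ureteric segments, kidney signalling, the gonads, ducts and adrenal glands, neighbouring tissues and general cell states. With a correlation estimated per list no list passed, the lowest adjusted p was 0.0951 and 10 lists had an unadjusted p under 0.05; by fry, which asks whether the genes of a list move one way, 10 lists passed. List means per array were compared by an exact two-sided permutation test, whose smallest p is 0.00794 for 5 against 5 pools and 0.0286 for 4 against 4.

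The genes named in the text follow a rule fixed before the data were examined: Wnt9b, the 12 largest rises and 12 largest falls among genes past the threshold, leaving out Xist and the Y-linked list, and for each list up to 5 genes past the threshold or, where fewer than 2 passed, the 2 with the smallest p. Alternatives concerned the probe set chosen per gene, filters on dim genes, the normalization between arrays, the floor, the replicate number as a block, Y-linked or Xist levels as covariates, the variance model, array weights, the kind of list test and leaving out each pool. Fits without the 2 arrays of high actin ratio, without the 3 Xist-high pools and with the actin ratio as a covariate, the exact test of list means, and 3 further lists (interferon-stimulated genes, and the smooth and skeletal parts of the muscle list) were chosen after seeing the data. The comparisons of the proximal tubule list with other lists were not set beforehand either.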

Results

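Gene expression was measured in urogenital systems dissected from mouse embryos at embryonic day 15.5. At this stage the kidney is forming nephrons beside the gonads, the reproductive ducts, the adrenal glands and the bladder. Levels of adrenal and testis genes differed between pools of the same genotype, as given below. RNA pools of 1 to 2 urogenital systems each were labelled and hybridized to Affymetrix arrays. The 10 arrays form 2 groups of 5 pools. Embryos of the first group carried the cneo allele of Wnt9b on both chromosomes and are called homozygous here. Embryos of the other group are called control; their genotype label gives 1 cneo and 1 normal allele, while their titles and the series title call them wild type. Wnt9b is a secreted Wnt ligand of the Wolffian duct and ureteric bud that is needed for nephron formation. The comparison asks which transcripts of the urogenital system differ between the 2 genotypes at this stage. The deposited values are intensities with the same trimmed mean, 500, on every array, and the number of arrays limits the precision.

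Wnt9b itself (GRCm38.p6, chromosome 11, 103727362 to 103775272) did not differ detectably between the genotypes. The brighter of its 2 probe sets had a mean log2 intensity of 6.83 ± 0.82 (SD, n = 5) in homozygous pools and 7.05 ± 0.11 (SD, n = 5) in control pools. The log2 difference was -0.23 ± 0.36 (SE), with an adjusted p of 0.803 in limma and an exact two-sided permutation p of 0.667. The lowest value, 47.79 on the linear scale, was in homozygous pool 3 and the highest, 201.04, in homozygous pool 5, so the homozygous pools lay on both sides of the control range of 120.78 to 143.44. The second probe set was at the floor of 16 on 6 of the 10 arrays. The labels do not give the part of the gene that the allele alters, so neither probe set can check the genotype labels.

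The pools differed in 2 further respects. Xist, the transcript of the inactive X chromosome, lay between 13.75 and 14.27 (log2) in homozygous pools 3, 4 and 5 and at 6.07 or below in the other 7 pools. The list of Y-linked genes had the opposite pattern, with a mean at the floor of 4.00 in those 3 pools and between 9.75 and 10.31 in the rest. The ratio of the 3' to the middle probe set of actin, a measure of RNA integrity, was 97.67 in homozygous pool 5 and 94.77 in control pool 1, against 9.87 to 33.13 in the other 8.

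**Figure D1:**
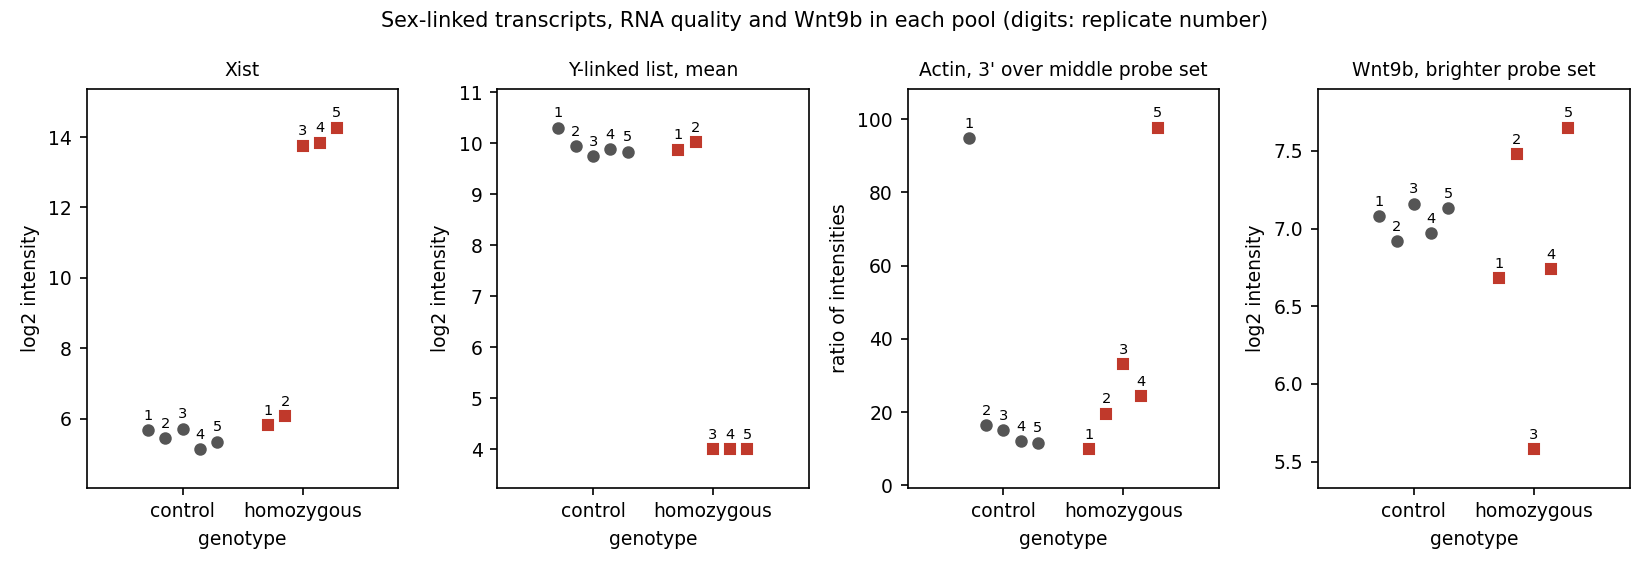
Values of each pool by genotype, with the replicate number above each point: Xist, the mean of the Y-linked list and the brighter Wnt9b probe set as log2 intensity, and the 3' over middle ratio of actin on a linear axis. Homozygous pools 3, 4 and 5 have high Xist and no Y-linked signal, homozygous pool 5 and control pool 1 have actin ratios of 97.67 and 94.77, and Wnt9b values of the 2 genotypes overlap.

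Across 18193 genes, 176 changed between the genotypes (limma, adjusted p under 0.05), 98 of them higher and 78 lower in homozygous pools. The largest rises included genes of sympathetic neurons and catecholamine synthesis, and the largest falls included transporters and enzymes of the kidney's proximal tubule. Slc6a2, the noradrenaline transporter, rose by 4.63 ± 0.87 on the log2 scale (SE; adjusted p = 0.0489), from 6.07 ± 1.82 (SD, n = 5) in control pools to 10.70 ± 0.96 (SD, n = 5) in homozygous pools. The 3 dimmer probe sets of Slc6a2 differed by 0.76, 0.47 and 0.28, and the mean of its probe sets by 1.53. S100g, the calcium-binding protein calbindin-D9k, fell by 2.67 ± 0.37 on the log2 scale (SE; adjusted p = 0.0295), from 10.87 ± 0.46 (SD, n = 5) to 8.20 ± 0.74 (SD, n = 5). Changes of at least 2-fold made up 67 of the rises and 49 of the falls.

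Beside Slc6a2, the 12 largest rises included Npy (2.79 ± 0.35, adjusted p = 0.0222), the neuropeptide of sympathetic neurons, and Gch1 (2.44 ± 0.32, adjusted p = 0.0251), which makes the cofactor of catecholamine synthesis. The neuronal intermediate filament gene Ina rose by 3.33 ± 0.63 and the peripheral neuron homeobox gene Hmx1 by 3.74 ± 0.52. The T-box gene Tbx20 (4.43), the G protein signalling regulator gene Rgs4 (3.87), the G protein subunit gene Gng4 (2.96), the ryanodine receptor gene Ryr2 (2.72), Tlcd3b (2.68) and Vstm2l (2.56) were the others of these, with Xaf1. Xaf1, which encodes a binding partner of the apoptosis inhibitor XIAP, rose by 3.98 ± 0.44 (adjusted p = 0.0222) from a control level of 4.48 at the floor on 2 arrays, while its second probe set differed by -0.76. Slc6a2, Tbx20, Rgs4 and Hmx1 were each at the floor on 1 control array, so their folds understate the change and their order is not certain. The dimmer probe sets of Tbx20 differed by 1.12 and 0.15, and those of Rgs4 by 1.24 and 0.11.

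Among the 12 largest falls, the ammonia transporter gene Rhbg dropped by 2.17 ± 0.15 (adjusted p = 0.00119) to the floor on 3 of 5 homozygous arrays, so that its fall is understated. The remaining falls were in Defb1 (-2.11), the glucuronosyltransferase genes Ugt2b5 (-2.09) and Ugt2b38 (-1.98), the cytochrome P450 genes Cyp2j5 (-2.06) and Cyp4a31 (-1.80), the brush border genes Vil1 (-1.93) and Mep1b (-1.77), and the solute carrier genes Slc5a8 (-1.91), Slc22a19 (-1.83) and Slc7a13 (-1.80). A second probe set of Slc7a13 differed by 0.44.

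**Figure D2:**
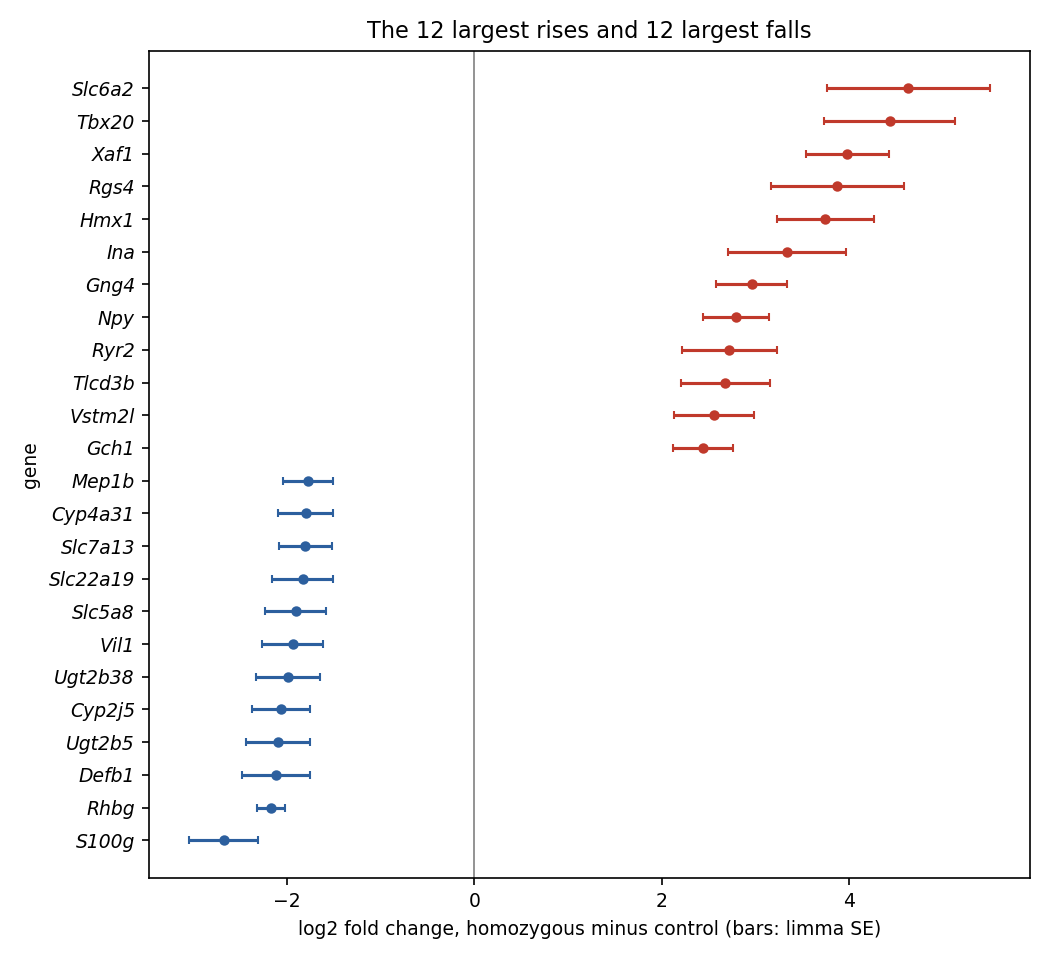
Log2 fold change, homozygous minus control, of the 12 genes with the largest rise and the 12 with the largest fall among those with adjusted p under 0.05, with bars for the standard error from limma. Rises run from 2.44 for Gch1 to 4.63 for Slc6a2 and falls from -1.77 for Mep1b to -2.67 for S100g.

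In all 176 genes every homozygous pool lay on the same side of every control pool. Of all genes 4.71% separated this way, against 0.794% expected by chance on average over groupings. Genes that vary together between pools can separate together, so this excess alone does not show an effect of the genotype. The number that passed the threshold hinged on single pools: it was 11, 250, 3, 67 and 13 without homozygous pools 1 to 5, and 13, 414, 3, 10 and 5 without control pools 1 to 5. Without both arrays of high actin ratio 23 genes passed, 10 of them among the 176. Without the 3 Xist-high pools 28 passed, 9 of them among the 176. All 24 of the largest changes kept their sign in both fits, an outcome that the separation of the pools fixed in advance. Without the 2 arrays these 24 kept 80.5% to 105% of their log2 change, though only Rhbg and Xaf1 of them passed with fewer pools. With the Y-linked or the Xist level as a covariate, 13 genes passed, 4 of them among the 176 in each fit.

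Gene lists fixed beforehand were tested with camera, which compares a list with all other genes, and 16 of 43 lists differed between the genotypes, 11 lower and 5 higher in homozygous pools. With an estimated correlation 0 of the 43 passed camera, with a lowest adjusted p of 0.0951 and 10 lists at an unadjusted p under 0.05. The proximal tubule list fell, with a median log2 change of -1.22 over 18 measured genes (adjusted p = 1.79e-11; adjusted p = 0.0951 with an estimated correlation). Of these genes 8 fell and 10 did not pass, and 14 fell when adjusted over the list alone. The endocytic receptor genes Lrp2 (-1.73) and Cubn (-1.45) fell with their partner Amn (-1.47), as did Hnf4a (-1.51), a transcription factor of proximal tubule cells, and the phosphate transporter gene Slc34a1 (-1.17). For Hnf4a, 2 dim probe sets differed by 0.29 and 0.02, and the other 2 were lower. The mean of the list was 7.89 ± 0.25 (SD, n = 5) in homozygous pools and 8.88 ± 0.25 (SD, n = 5) in control pools, an exact two-sided permutation p of 0.00794, the smallest that 5 against 5 pools can give. The difference was -0.97 without both arrays of high actin ratio, where none of its genes passed by themselves.

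The list of loop of Henle and distal tubule genes had a median of -1.01 over 14 genes (adjusted p = 2.09e-06; adjusted p = 0.0951 with an estimated correlation). None of its genes passed over all genes, and 9 fell and 1 rose when adjusted over the list alone. The call was lost with the dimmest 60% of genes left out (median -0.42, adjusted p = 0.101). Kcnj1 differed by -1.29 (adjusted p = 0.0535) and Sim1 by -1.44 (adjusted p = 0.0788). The early nephron list, which covers pretubular aggregates to S-shaped bodies, had a median of -0.62 over 17 genes (adjusted p = 5.15e-07; adjusted p = 0.0951 with an estimated correlation). In it Dkk1 (-1.63) and Cdh6 (-0.80) fell, 15 genes did not pass, and 7 fell when adjusted over the list alone. Dkk1 encodes a secreted Wnt inhibitor and Cdh6 a cadherin of the forming tubule. A dimmer probe set of Cdh6 differed by -0.014. The podocyte list had a smaller median of -0.37 over 11 genes, none of which passed (adjusted p = 0.0169; adjusted p = 0.109 with an estimated correlation), and 1 fell when adjusted over the list alone. Its genes Clic5 and Podxl differed by -1.11 and -0.75. The podocyte call was lost without the 3 Xist-high pools (adjusted p = 0.0599), where the difference of list means was -0.24 against -0.38 over all pools. It was also lost with the Xist level as a covariate (median -0.21, adjusted p = 0.0698) and with the dimmest 60% of genes left out (adjusted p = 0.086).

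Taken per pool, the proximal tubule mean fell relative to the nephron progenitor list by 0.51, relative to the podocyte list by 0.61 and relative to the renal stroma list by 1.11 on the log2 scale (adjusted p = 0.0185 for each, exact permutation tests over 7 lists). It also fell relative to the early nephron, loop and collecting duct lists, with adjusted p of 0.0417, 0.0444 and 0.0463 in the same exact tests. Without both arrays of high actin ratio the difference was -0.26 against the loop list and -0.36 against the collecting duct list, compared with -0.23 and -0.41 over all pools, while the exact permutation p over the 8 remaining pools was 0.0571 and 0.114. It was 0.0286, the smallest that 4 against 4 pools can give, against the nephron progenitor, podocyte, renal stroma and early nephron lists. Relative to the ureteric tip list its difference was -0.28, which did not pass (exact permutation adjusted p = 0.0635). These comparisons were not set beforehand. The proximal tubule list had the lowest adjusted p of the 43 lists in camera, and the p-values here do not allow for that choice.

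The nephron progenitor list had a median of -0.46 over 14 genes (adjusted p = 0.00177; adjusted p = 0.287 with an estimated correlation). No gene of it passed over all genes and 4 fell when adjusted over the list alone, with Uncx, a homeobox gene, at -1.41 and Crym at -0.86. Candidate Wnt9b target genes recalled from earlier work were lower in 8 of 8 cases, with a median of -0.87 (adjusted p = 3.62e-04; adjusted p = 0.0951 with an estimated correlation). None of these 8 passed over all genes and 3 fell when adjusted over the list alone. The difference of list means was -0.75 for the candidate targets, while nephron and ureteric lists ran from -0.38 (podocyte) to -0.996 (proximal tubule). Whether the fall was particular to Wnt9b targets was not tested. Uncx, Crym, Cited1 and Itga8 belong to both lists. The feedback targets of canonical Wnt signalling did not pass camera (adjusted p = 0.22), but their mean was 8.49 ± 0.15 (SD, n = 5) in homozygous pools and 8.74 ± 0.03 (SD, n = 5) in control pools, with every homozygous pool below every control pool (exact permutation adjusted p = 0.031 over 43 lists). Over the 31 alternatives, adjusted p ran from 0.0097 to 0.806 and 4 passed, among them camera without the 3 Xist-high pools (adjusted p = 0.0097). Of the 14 genes of this list only Dkk1 fell, against 2 adjusted over the list alone; Rnf43 differed by -0.68. The planar cell polarity list did not differ either (adjusted p = 0.363): none of its 22 genes passed, 3 rose and 3 fell when adjusted over the list alone, and Celsr3 and Celsr2 differed by 2.41 and -0.61.

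The ureteric tip list had a median of -0.67 over 11 genes (adjusted p = 5.73e-06; adjusted p = 0.0951 with an estimated correlation). Gfra1, a co-receptor for the growth factor GDNF, fell by 0.97 on the log2 scale, while its dimmer probe sets differed by -0.34 and -0.001. In this list 10 genes did not pass, and 5 fell when adjusted over the list alone, and Myb differed by -1.26. The collecting duct list had a median of -0.69 over 18 genes, none of which passed (adjusted p = 9.27e-05; adjusted p = 0.2 with an estimated correlation). In this list 5 genes fell when adjusted over the list alone. Its genes Elf5 and Calb1 differed by -1.27 and -1.15. The list of FGF, GDNF and BMP signals had a median of -0.17 over 20 genes (adjusted p = 0.00296; adjusted p = 0.0951 with an estimated correlation); Gfra1 was its only gene past the threshold, 5 fell when adjusted over the list alone, and Bmp7 differed by -0.74. The cell cycle list had a median of -0.19 over 17 genes (adjusted p = 0.00357; adjusted p = 0.0951 with an estimated correlation), with no gene past the threshold on either count. Its genes Aurkb and Mcm5 differed by -0.33 and -0.21. Its difference of list means was -0.22 over all pools, -0.17 without both arrays of high actin ratio and -0.098 without the 3 Xist-high pools. Its lowest mean was 10.77 in homozygous pool 5, against 11.02 to 11.19 in the other homozygous pools. The renal stroma list did not differ (adjusted p = 0.495): none of its 17 genes passed, 1 rose and 1 fell when adjusted over the list alone, and Aldh1a2 and Meis1 differed by -0.49 and 0.44.

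Against these falls, the list of neuronal and chromaffin cell genes rose, with a median of 2.77 and all 15 genes higher in homozygous pools (adjusted p = 3.25e-09; adjusted p = 0.213 with an estimated correlation). None of the 15 passed over all genes and 13 rose when adjusted over the list alone. Phox2a, a transcription factor of noradrenergic neurons, differed by 3.07 (adjusted p = 0.0558) and the noradrenaline-synthesizing enzyme gene Dbh by 3.34 (adjusted p = 0.0602). The list mean was 10.05 ± 0.62 (SD, n = 5) in homozygous pools and 7.41 ± 1.34 (SD, n = 5) in control pools, where it ranged from 5.69 to 9.08. The muscle list was higher in 16 of 16 genes with a median of 1.98 (adjusted p = 4.70e-05; adjusted p = 0.287 with an estimated correlation), with no gene past the threshold on either count. Acta2 and Cnn1 of smooth muscle differed by 0.84 and 2.49. The adrenal cortex list was higher in 12 of 12 genes with a median of 1.41 (adjusted p = 0.00609; adjusted p = 0.491 with an estimated correlation), again with no gene past the threshold on either count and Nr0b1 and Hsd3b1 at 1.49 and 4.08. Its mean per pool ran from 5.81 in control pool 1 to 10.79 in homozygous pool 2. Its call was lost without both arrays of high actin ratio (adjusted p = 0.143, difference of list means 1.27 against 1.77 over all pools), without control pool 1 (adjusted p = 0.0694), without control pool 2 (adjusted p = 0.0543) and without the 3 Xist-high pools (adjusted p = 0.0613). With array weights the adrenal call was lost too (median 0.68 against 1.41, camera adjusted p = 0.325).

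The macrophage list had a median of 0.44 over 13 genes (adjusted p = 0.00391; adjusted p = 0.287 with an estimated correlation). Adgre1, which encodes a macrophage surface marker, rose by 0.67 and Csf1r, the receptor for colony-stimulating factor 1, by 0.60; 11 genes did not pass, and 4 rose when adjusted over the list alone. The hypoxia and glycolysis list had a median of 0.36 over 13 genes (adjusted p = 0.0445; adjusted p = 0.594 with an estimated correlation), with no gene past the threshold on either count and Adm and Aldoa at 1.60 and 0.36. Its mean was 12.17 in homozygous pool 5 and 10.40 to 10.65 in the other 9 pools, and its median was -0.04 without both arrays of high actin ratio (adjusted p = 0.992). The hypoxia call was lost without homozygous pool 5 (adjusted p = 0.906), and also without control pools 1, 2, 3 or 5, with adjusted p of 0.115, 0.0505, 0.0504 and 0.0565. Other camera fits lost it too, among them the Xist covariate (median 0.097, adjusted p = 0.959) and the Y-linked covariate (0.15, adjusted p = 0.761). So did array weights (0.041, adjusted p = 0.432), the mean of all probe sets (0.24, adjusted p = 0.075) and the fit without the 3 Xist-high pools (0.15, adjusted p = 0.421). The Y-linked list had a median of -3.67 over 3 genes (adjusted p = 0.0125; adjusted p = 0.333 with an estimated correlation); none passed over all genes, 3 fell when adjusted over the list alone, Uty and Kdm5d differed by -3.03 and -3.67, and without the 3 Xist-high pools the median was -0.05 (adjusted p = 0.988). The Y-linked call was also lost without both arrays of high actin ratio (adjusted p = 0.137), with a difference of list means of -2.88 against -3.57 over all pools. Xist differed by 5.29 (adjusted p = 0.203 in limma).

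None of the 16 lists passed camera with an estimated correlation, and some did not pass the other list tests either. By fry the adjusted p was 0.0625 for muscle, 0.0697 for nephron progenitors, 0.0513 for collecting duct, 0.223 for adrenal cortex, 0.462 for hypoxia and glycolysis and 0.101 for the Y-linked list. By the exact permutation test of list means it was 0.10 for muscle, 0.0788 for nephron progenitors, 0.0569 for podocytes, 0.133 for macrophages, 0.218 for adrenal cortex, 0.179 for hypoxia and glycolysis and 0.193 for the Y-linked list. The exact test called 11 lists, 9 of them among the 16; the others were the Wnt feedback and the cystic kidney disease lists.

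**Figure D3:**
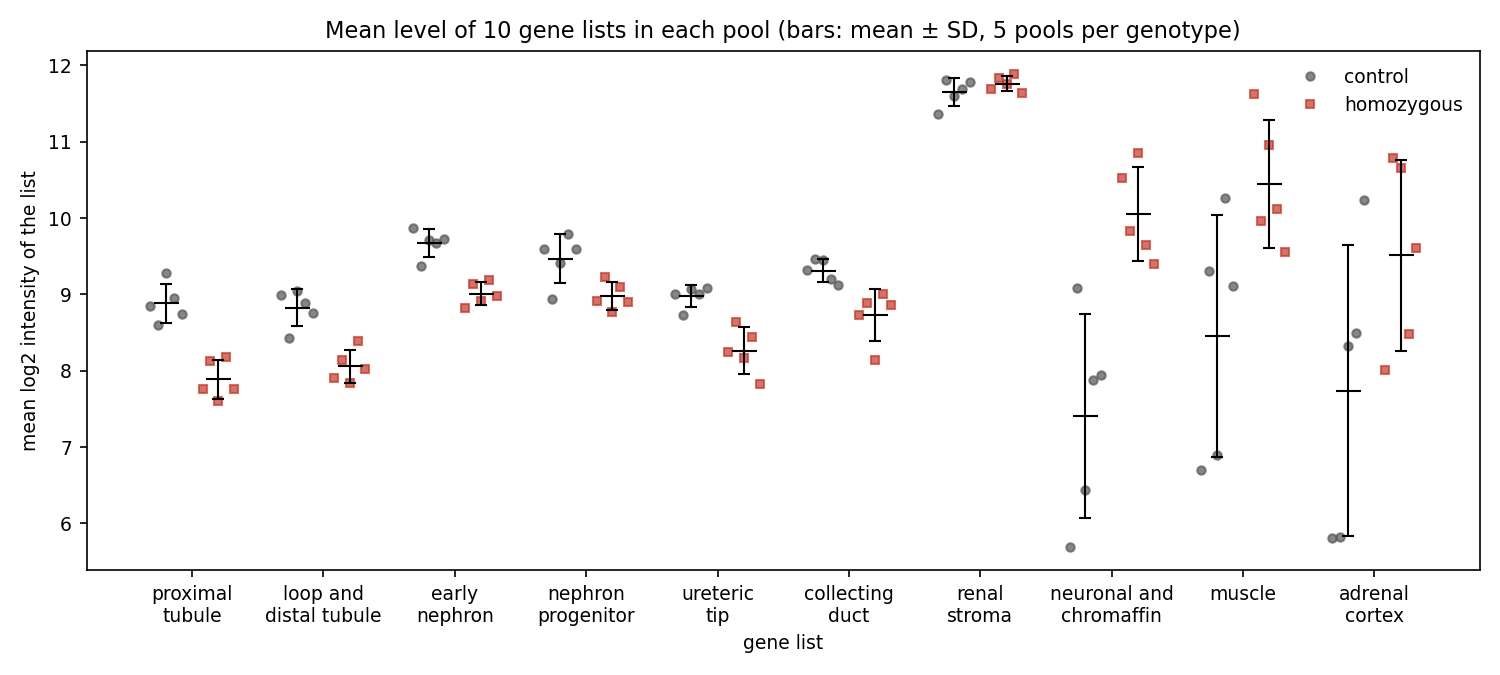
Mean log2 intensity of 10 gene lists in each pool, with bars for the mean ± SD of the 5 pools of a genotype. The proximal tubule list lies between 7.61 and 8.18 in homozygous pools and between 8.61 and 9.28 in control pools, while the neuronal and chromaffin, muscle and adrenal cortex lists spread widely among control pools.

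The other lists did not pass camera, and apart from Vil1 in the list of liver, gut and pancreas genes none of their genes passed over all genes. Adjusted p was 0.0585 for the kidney injury list, with Ccn2 and Fn1 at 1.30 and 0.40, and 0.0585 for immediate early genes, with Junb and Fos at -0.97 and 1.49, where 1 gene fell when adjusted over the list alone. It was 0.0679 for nerve glia (Fabp7 2.09, Foxd3 0.98), 0.0744 for genes mutated in cystic kidney disease (Umod -1.27, Glis3 -0.81) and 0.0744 for red blood cells (Hba-x 0.71, Hbb-bh1 0.70). The mean of the cystic kidney disease list did differ in the exact permutation test (difference -0.23, adjusted p = 0.031), and its adjusted p over the 31 alternatives ran from 0.031 to 0.287, with 5 past the threshold, among them camera without control pool 4 (adjusted p = 0.0416). Extracellular matrix genes had an adjusted p of 0.0814, with Mmp2 and Col5a1 at 0.50 and 0.76, and 6 of them rose and 1 fell when adjusted over the list alone. The values were 0.0876 for heat shock and unfolded protein genes (Hspb1 1.02, Ddit3 0.43), 0.142 for bladder lining (Upk1b 1.69, Upk3b 1.31), 0.257 for mesothelium (Muc16 1.39, Lrrn4 1.20), 0.319 for p53 targets (Pmaip1 1.01, Ccng1 0.27) and 0.319 for blood vessels (Eng 0.44, Plvap -0.57). Notch pathway genes had an adjusted p of 0.148, with Dll1 and Notch3 at -0.78 and 0.21, and 2 of them rose and 1 fell when adjusted over the list alone. Genes near Wnt9b had 0.327 (Cdc27 -0.14, Mapt 0.74), skeletal tissue 0.363 (Matn1 -1.55, Col9a1 -0.82), ribosomal proteins 0.409 (Rpl19 0.13, Rpl4 0.10), fat 0.531 (Lpl 0.38, Adipoq 0.28), reference genes 0.713 (B2m 0.36, Tfrc -0.31) and mitochondrial respiration 0.826 (Ndufa4 0.17, Idh3a -0.51). Adjusted over the list alone, 1 gene rose among nerve glia and 1 among reference genes, and none passed in the rest of this group.

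Of the 27 lists that did not pass camera, 13 passed under at least 1 alternative. Leaving out a single pool was enough for 7 of them. The kidney injury list passed without homozygous pools 2, 3 or 4 or control pools 4 or 5 (adjusted p of 0.0431, 0.031, 0.0353, 0.0314 and 0.034), and over its 31 alternatives adjusted p ran from 0.00277 to 0.287. Immediate early genes passed without homozygous pools 2, 3 or 4 or control pool 4 (0.0469, 0.0436, 0.0354 and 0.0251; range 0.00523 to 0.287), and nerve glia without control pools 2, 4 or 5 (0.0114, 0.0296 and 0.0365; range 0.0114 to 0.519). Red blood cells passed without control pools 3 or 4 (0.0367 and 0.00733; range 0.00733 to 0.448), extracellular matrix without control pools 4 or 5 (0.032 and 0.0365; range 0.00369 to 0.448), and bladder lining without homozygous pool 3 or control pool 2 (0.0393 and 9.63e-04; range 9.63e-04 to 0.594). The seventh was the cystic kidney disease list.

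Lists of the gonads and ducts varied between pools of both genotypes and did not pass camera in the main fit. Adjusted p was 0.142 for fetal Leydig cells (Hsd3b1 4.08, Vcam1 0.46), 0.57 for Sertoli cells (Sox9 -0.72, Nr5a1 2.55), 0.521 for germ cells (Stra8 0.49, Sycp3 1.70) and 0.476 for fetal ovary (Irx5 -0.61, Bmp2 -0.80), with no gene past the threshold on either count. Without the 3 Xist-high pools the difference of Sertoli list means was 1.65 against 0.46 over all pools (camera adjusted p = 0.0469), and that of the germ cell list was 1.29 against 0.39 (camera adjusted p = 0.0613). With the Y-linked or the Xist level as a covariate, adjusted p was 0.0185 and 0.0113 for Sertoli cells, 0.0405 and 0.0344 for germ cells, and 0.0457 and 0.043 for Leydig cells. Over all alternatives it ran from 0.0113 to 0.972, from 0.0344 to 0.998 and from 0.0427 to 0.532 for the 3 lists. The reproductive duct list had an adjusted p of 0.148 in the direction of its median, -0.23, while its mean difference was 0.17. In it Lhx1, shared with the early nephron, differed by -1.57 (adjusted p = 0.0558) and Amhr2 by 2.56, and 1 gene rose and 3 fell when adjusted over the list alone. With the dimmest 60% of genes left out the duct list passed camera (median -0.53, adjusted p = 0.00382). For liver, gut and pancreas genes the test pointed down (adjusted p = 0.979) while the median was 0.29 and 1 gene fell when adjusted over the list alone, and for genes near Wnt9b the median was -0.11 and the mean difference 0.10.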

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

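The test of other groupings of the pools was set before its result was seen. The tests of tissue carry-over, kidney share, RNA quality, fetal sex, smooth and skeletal muscle, chromosome 11 and the window around Wnt9b were chosen after the results they concern had been seen. A value far from the rest of its group was looked for in 308 groups of 5 pools, of which about 1 in 20 would show one by chance; 26 did, 6 of them in homozygous pool 5, 6 in control pool 1 and 5 in control pool 2.

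Both arrays of high actin ratio stood apart from their group, at 97.67 in homozygous pool 5 and 94.77 in control pool 1. Homozygous pool 5 was also high in the hypoxia and glycolysis list (12.17 against 10.45 to 10.65 in the other homozygous pools), Adm (11.51), Pmaip1 (9.18) and Ddit3 (8.59), and low in the planar cell polarity list (9.04 against 9.40 to 9.46). Control pool 1 was high in Aldh1a2 (12.79), Glis3 (9.57) and Aldoa (12.97), and low in Lrrn4 (4.60) and in the reference gene list (11.88 against 12.09 to 12.11).

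Control pool 2 was high in the bladder lining list (9.52 against 6.89 to 7.54 in the other controls), Vil1 (9.96), Celsr3 (6.63) and the hypoxia and glycolysis list (10.56), and low in the ureteric tip list (8.73). Control pool 5 was high in the skeletal tissue list (9.999 against 5.62 to 6.43), Matn1 (11.11), Col9a1 (13.37) and Adipoq (4.49), and control pool 4 in the liver, gut and pancreas list (8.95 against 6.80 to 7.26). Single values stood apart for Rhbg in homozygous pool 4 (4.74, the others at 4.00 to 4.12), Adgre1 in homozygous pool 3 (9.22) and Cdc27 in homozygous pool 2 (11.20). The second Wnt9b probe set was at 4.13 in control pool 3, with the other controls at the floor. Among 10092 probe sets without a single gene name, which the comparison of genes leaves out, 8 were higher and 10 lower in homozygous pools (limma over all probe sets, adjusted p under 0.05); their log2 differences ran from -3.84 to 3.26.

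The number of genes past the threshold was not matched by other groupings drawn. Among 100 of the 126 splits of the pools into 5 and 5, only 1, the genotype split, gave 176 genes or more. The highest other split gave 100, and it set homozygous pools 1, 3, 4 and 5 with control pool 2 against the rest. A chance imbalance of the pools between genotypes is not excluded by this, since all 3 Xist-high pools were homozygous.

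The proximal tubule list was lower in homozygous pools, with a difference of list means of -0.996 on the log2 scale. With the mean of the neuronal, muscle and adrenal lists as a covariate, the difference was -0.81 (95% interval from a linear model, -1.42 to -0.20). That mean was higher in every homozygous pool than in every control pool. The adjusted difference is therefore an extrapolation and cannot decide whether carry-over of these tissues was the cause. Without both arrays of high actin ratio the difference was -0.97, which argues against these 2 arrays as the whole cause. The remaining actin ratios were 9.87 to 33.13 in homozygous and 11.62 to 16.36 in control pools, so RNA quality in general is not excluded. Over the pools with Y-linked transcripts the difference was -0.94. There the higher of the 2 homozygous pools (8.13) lay below the lowest control pool (8.61), which argues against fetal sex as the whole cause. The list fell further than the podocyte list by 0.61 (exact permutation p = 0.00794) and than the loop and distal tubule list by 0.23 (difference -0.23, exact permutation p = 0.0317; -0.26 and 0.0571 without both arrays), which an equal dilution of genes made by kidney alone would not give. A smaller share of kidney nevertheless cannot be told apart from fewer or later tubules, since these lists hold genes that go another way, such as Ptger3 (1.36) beside Kcnj1 (-1.29), Umod (-1.27) and Slc12a1 (-1.12) in the loop list, and it is not known which of them other tissues express here.

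The neuronal and chromaffin list was higher in homozygous pools by 2.64 on the log2 scale. Adjusted for the adrenal cortex list, the difference was 2.52 (95% interval 0.57 to 4.46), and without both arrays of high actin ratio 2.38. These values argue against carried-over adrenal glands and against those 2 arrays as the whole cause, while RNA quality in general is not excluded. Among control pools alone the list spanned 3.39 log2 units, from 5.69 to 9.08, more than the difference between genotypes, and homozygous pools lay between 9.39 and 10.86. Uneven dissection of ganglia and nerves therefore cannot be told apart from an effect of the genotype on sympathetic tissue, because the amount of attached tissue was not recorded in the labels. The smooth muscle genes of the muscle list differed by 1.77 (exact permutation p = 0.0238), and by 1.59 without both arrays (exact permutation p = 0.0857 over 8 pools), and the skeletal muscle genes by 2.21 (exact permutation p = 0.175).

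The embryos may differ in strain DNA linked to the altered Wnt9b locus, which would place genes past the threshold on chromosome 11. Of 1452 tested genes on this chromosome 12 passed, against 176 of 18140 genes with a known chromosome (odds ratio 0.84, 95% interval 0.424 to 1.51, Fisher's exact p = 0.675). Within 20 megabases of Wnt9b, a window set after the genes on the chromosome and the nearest neighbours had been looked at, 4 of 645 genes passed (odds ratio 0.629, 95% interval 0.169 to 1.65, Fisher's exact p = 0.535). These values argue against linked strain DNA as the source of the changes as a set, and for single genes it stays open, among them Rsad1 (-1.47), Aoc3 (1.58), Krt222 (1.11) and Cacng5 (1.57) inside the window and Xaf1 (3.98) outside it. Rsad1 and Xaf1 each have probe sets that moved in opposite directions.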

How the results depend on the processing

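The fits without the 2 arrays of high actin ratio, without the Xist-high pools and with the actin ratio as covariate, and the exact test of list means, were chosen after seeing the data. The count of genes depended on the setting and that of lists less so; the cause was not tested, except that fewer pools or genes enter some fits. Against 176 genes (55.7% higher), 109 changed with the mean of all probe sets, 283 and 108 without the dimmest 40% and 60% of genes, 94 with a floor of 32 (48.9% higher), 13 with the Y-linked and 13 with the Xist covariate (92.3% higher in each), 951 with array weights, 104 of all probe sets tested singly, 23 without the 2 arrays of high actin ratio, 489 with the actin ratio as covariate and 28 without the Xist-high pools (89.3% higher). Leaving out 1 pool gave 3 genes (without homozygous or control pool 3) to 414 (without control pool 2), 14 to 22 lists and a Wnt9b difference of -0.43 to 0.09. Other settings gave 168 to 250 genes. Same-numbered pools did not deviate together (correlations -0.553 to -0.172), which gives no sign of a pairing by number but does not exclude one. With the replicate block 1 gene and 19 lists changed. Against 16 lists, 0 passed by camera with an estimated correlation (10 at an unadjusted p under 0.05), 10 by fry and 13 to 22 in all other fits, except 11 in the exact test.

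Wnt9b passed in no fit. Its difference turned to 0.10 with the mean of all probe sets, 0.031 with the Y-linked and 0.0068 with the Xist covariate, 0.086 without homozygous pool 3 and 0.029 without the Xist-high pools. None of the 34 named genes past the threshold changed sign, which in fits that only leave out pools was fixed by their separated pools. Of 924 refits 457 kept these genes past the threshold, and 1, Rhbg, passed in every fit that left out a pool. Signs turned only for genes and lists that did not pass there, as follows. Mean of all probe sets: Notch3 -0.37, Eng -0.018, Cdc27 0.16, genes near Wnt9b 0.030, ribosomal proteins -0.0057. Quantile normalization: Rpl4 -0.030 and ribosomal proteins -0.030. Dim genes left out: mesothelium -0.14 at 40%, reference genes 0.0070 at 60%. Y-linked covariate: planar cell polarity 0.0017, genes near Wnt9b 0.057. Xist covariate: Uty 0.20, Kdm5d and the Y-linked list 0.29, Rpl4 and ribosomal proteins -0.017, blood vessels 0.042, genes near Wnt9b 0.12, reference genes 0.029. Array weights: Sertoli -0.15, germ cells -0.22. Xist-high pools left out: Rpl4 and ribosomal proteins -0.0037, genes near Wnt9b 0.085. Arrays of high actin ratio left out: hypoxia and glycolysis -0.040, mitochondrial respiration 0.00063. A pool left out: mitochondrial respiration from -0.046 to 0.064, above 0 without homozygous pools 1, 2 or 4 (0.0084, 0.037 and 0.029) or control pool 1 (0.064), germ cells from -0.032 (without control pools 1, 2 or 4) to 0.60, and skeletal tissue from -1.05 to 0.31 (without control pool 5). No depth is known; near the floor, where 19.9% to 23.0% of probe sets lie, changes are understated. The Y-linked list had no value without the dimmest 60% of genes, nor did other lists that a filter on dim genes left with fewer than 3 genes.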

Other observations

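The test of interferon-stimulated genes was chosen after results were seen. Solute carrier genes, which encode membrane transporters, were singled out after the largest falls had been seen, so their number was not tested. Of 347 solute carrier genes, 7 fell and 2 rose. The 7 were Slc22a19 (-1.83), Slc5a8 (-1.91), Slc7a13 (-1.80), Slc52a3 (-1.63), Slc5a1 (-1.58), Slc34a1 (-1.17) and Slc27a2 (-1.14), and Slc5a8, Slc34a1 and Slc27a2 are also in the proximal tubule list.

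Genes linked to immune cells and interferon appeared among the rises, and were singled out after their values were seen: Gbp2 rose by 2.05 ± 0.25, Casp12 by 1.23 ± 0.15 and Sirpb1a by 1.23 ± 0.16 on the log2 scale (limma SE, adjusted p = 0.0222 for each). A list of interferon-stimulated genes, written because Gbp2 and Ifi35 had been noticed and with Ifi35 in it, was higher in homozygous pools by 0.30 (exact permutation p = 0.0159), with 12 of 19 genes higher. Without Ifi35 the difference was 0.26 (exact permutation p = 0.0238). No gene of the list passed over all genes in limma and 6 had an unadjusted p under 0.05; Ifi35 (0.89, adjusted p = 0.0507), Gbp7 (0.74, adjusted p = 0.0558) and Gbp3 (1.30, adjusted p = 0.0812) came closest. Without both arrays of high actin ratio the exact permutation p was 0.0571 and the difference 0.29. The genes of the list went both ways: 7 of 19 were lower, among them Rsad2 (-0.57), Bst2 (-0.29) and Oas1a (-0.22), and without Ifi35 the median was 0.11 with an SD of 0.50 between genes. These values do not decide whether an interferon response was present.

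Testis and adrenal gland genes marked pools of both genotypes, but unevenly. The lowest adrenal values were in control pools alone, and so were the low Sertoli values among pools with Y-linked transcripts. Whether uneven dissection gave this was not tested. The Sertoli list was at 8.69 and 9.24 in homozygous pools 1 and 2 and at 8.85 and 9.01 in control pools 3 and 5, and at 7.07 or below in the other 6 pools, of which control pools 1, 2 and 4 had Y-linked transcripts. The adrenal cortex list was at 5.81 and 5.82 in control pools 1 and 2 and between 8.01 and 10.79 elsewhere. The probe set named for Sry was dim and was higher by 0.87 in homozygous pools in limma. It read 4.47 to 5.14 in the 3 homozygous pools without Y-linked signal, above the control range of 4.00 to 4.28. Its difference therefore cannot be read as a change of Sry transcript.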
